A study of Mus musculus with 4 samples.

How the data were processed

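Kidney sections of female and male mice from the Jackson Laboratory, at 12 and 92 weeks, were measured with the Xenium platform, with 1 section per sex and age. Per the file headers, the deposited matrices hold counts of decoded transcripts per feature and segmented cell, and the deposited cell tables hold counts per cell by kind of feature with cell positions and areas. The matrices list 479 genes, 20 negative control probes, 41 negative control codewords and 1 unassigned codeword. The sums per cell were checked against the cell tables and 0 cells differed. The settings of decoding, quality filtering and segmentation are not stated in the sources used here, and the unit of length was taken as micrometres from the platform. No normalization by the authors was found in the files. Gene symbols and Ensembl IDs are those of the files.

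The section totals were 75185621 gene transcripts (W12 female), 91374358 (W12 male), 115267493 (W92 female) and 119861711 (W92 male). Cells with fewer than 10 transcripts were left out, which kept 99.9% of cells in the W12 female section and 99.95%, 99.96% and 99.97% in the others, in the order above. Kept cells had medians of 55, 62, 63 and 66 genes and cell areas of 97.4, 121, 106 and 125 square micrometres. Doublets were not called, and transcripts that segmentation gave to a neighbouring cell were not removed.

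Transcripts were summed over kept cells and scaled by the total of panel transcripts to counts-per-million (CPM). Ratios are log2 of female over male within an age and of W92 over W12 within a sex, without a pseudocount. A gene was measured in a pair of sections if it had at least 300 transcripts in the richer of them, and was called by size, at 1.5-fold. With 1 section per group no p-value, standard error or test was made. An additive model of sex and age over the 4 sections was not made. Exact 95% Poisson intervals of sums and exact Clopper-Pearson intervals of shares cover counting error only.

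The rules that follow were set before the data were examined. Genes named were the 10 per direction, higher or lower in the same sense at both ages (or in both sexes, for age), with the largest smaller absolute ratio. They also included the 5 per direction whose sex ratio differed most between ages, the 6 per direction in proximal tubule-like cells, and the 2 per direction in each other named class. Members of the lists were named as examples. Some genes and lists that the rules name are not used here. Lists were male-biased and female-biased kidney genes, steroid and hormone receptors, proximal tubule transport and metabolism, tubular injury, extracellular matrix and fibrosis, B and plasma cell, T and NK cell, macrophage and dendritic cell, MHC class II, lymphoid organisation, interferon response, neutrophil, senescence and secretory phenotype, immediate early and heat shock, cell cycle, podocyte, thick ascending limb, distal tubule and connecting tubule, collecting duct, intercalated cell, endothelial, smooth muscle and pericyte, adipocyte, urothelium and adrenal. A list's median ratio was taken over its genes measured in every pair of sections. It was set against 10000 random lists of its size drawn from 10 bins of mean expression. Lists with fewer than 3 such genes were given gene by gene.

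Cells were classed by clustering 20000 cells per section, with counts scaled to 200 transcripts, logged and centred on the mean of each section. Leiden clustering at resolution 1 on 30 principal components and 15 nearest neighbours gave 31 clusters. All kept cells were then assigned to the most likely cluster under multinomial profiles that were specific to each section, with a pooled prior of 2000 transcripts, and 86.6% of the clustered cells were assigned back to their own cluster. Marker genes were set before the data were examined, and the rule that turns them into names was set after the clusters were seen. A cluster took the class with the most markers among its 10 leading genes by fold, if at least 3 markers were raised 1.5-fold and its 5 leading genes did not point to another class. Classes are called "-like", since they rest on transcripts alone. Aggregates of lymphoid-like cells were groups of at least 50 cells linked by DBSCAN at 50 micrometres with at least 10 neighbours. Grouped adipocyte-like cells were found with the same distance and neighbour number. They are called hilar fat here, without histology to check their place. Depth was measured in bins of 500 micrometres below the hull of the section.

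The steps were tested on simulated data made from the depths of the sections. At 2-fold, 100% of changed genes were recovered in each comparison. At 1.7-fold, 95.5% were recovered for sex at W12 (434 genes), 99.0% for sex at W92 (469 genes), 90.9% for age in females (433 genes) and 93.3% for age in males (442 genes). Of unchanged genes, 0 were called. The intervals covered the simulated ratio for 96.1%, 94.2%, 96.1% and 94.6% of genes in the same order. With 479 genes, 95.9% of simulated cells of named classes were returned to their class, 88.7% of proximal tubule cells and 46.9% of unnamed cells. These cells were drawn from the cluster profiles found in the same sections, without doublets or transcripts of neighbouring cells. The shares therefore do not measure accuracy on real cells.

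Alternatives set before the data were examined changed the filters on cells and genes, the scaling, the subtraction of background, the side of the section (split at the median x position), the threshold, the weight of the classes, the clustering, the depth, the use of clusters at all and the definition of an aggregate. Settings added after the data were seen left out cells within 200 micrometres of grouped adipocyte-like cells, left Prg2 out of the assignment, or kept genes at least 10 times the highest control probe. The last of these was run with that minimum in every section and with it on the mean. Splits of the samples and tests for outlying samples do not apply to single sections. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9, leidenalg 0.10.2, pyarrow 21.0.0 and matplotlib 3.10.9, with random seed 1.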

Results

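Transcripts of 479 genes were counted in segmented cells of mouse kidney sections with Xenium, an imaging assay that decodes single RNA molecules in place in fixed, paraffin-embedded tissue. There were 4 sections, 1 from each of a female and a male mouse at 12 weeks (W12) and a female and a male mouse at 92 weeks (W92). No group had replicates and no test was made, so variation between mice is not measured here. The intervals given are exact 95% intervals that cover counting error alone. The W12 female section held 75185621 gene transcripts in 336623 cells and the W12 male section 91374358 in 320131 cells. The W92 female section held 115267493 gene transcripts in 421140 cells and the W92 male section 119861711 in 397721 cells. Cells with at least 10 transcripts were kept. The median kept cell held 192 transcripts in the W12 female section, 239 in the W12 male, 235 in the W92 female and 253 in the W92 male. The panel held no Y-linked gene and no Xist, so the labelled sex could not be checked on such genes.

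The labels set the question of how expression in the kidney differs between females and males at each age. Ratios are log2 of female over male counts-per-million (CPM) of panel transcripts, so negative values are higher in the male. At W12, 428 genes had at least 300 transcripts in the richer section, of which 53 were at least 1.5-fold higher in the female section and 71 in the male. At W92, 470 genes were measured, with 31 higher in the female section and 48 in the male. Of the 428 genes measured in every pair of sections, 14 were higher in the female and 25 in the male at both ages. The share of calls that were higher in the female was 42.7% at W12 and 39.2% at W92. With mean transcripts per cell in place of CPM it was 11.6% and 23.9%, and the median of all genes was -0.34 and -0.09 in place of 0.01 and 0.05. Without cells near grouped adipocyte-like cells (hilar fat), a setting chosen after the data were seen, the share was 50.5% and 50.7%, so the male excess of calls depends on those cells.

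Prlr (ENSMUSG00000005268), which encodes the prolactin receptor, ranked first among genes higher in the female at both ages, ordered by the smaller of their ratios. Its log2 ratio was 5.83 (5.79 to 5.88) at W12 and 2.32 (2.30 to 2.33) at W92. Its level was 2556 CPM in the W12 female, 44.9 CPM in the W12 male, 2985 CPM in the W92 female and 599.5 CPM in the W92 male section. The calcium sensor gene Vsnl1 (ENSMUSG00000054459) was higher in the female by 2.14 at W12 and 2.40 at W92, and the cadherin gene Cdh6 by 1.53 and 2.08. The enzyme gene Aldh1b1 had 1.63 and 2.11, and Aadat (ENSMUSG00000057228) had 0.83 and 1.79. The remaining genes taken by the same rule were Prap1, Pcolce2, Nap1l5, Gria2 and Fam25c, with ratios from 0.82 to 2.28. Fam25c lay between 1.36 and 5.23 times the mean negative control probe in the sections. In the W12 and W92 male sections Vsnl1 lay at 2.31 and 2.73 times that mean and Prap1 at 3.31 and 4.08, and Gria2 lay at 3.45 in the W92 male section. These counts are close to background, which limits the ratios of the 4 genes.

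Hrg (ENSMUSG00000022877), which encodes a plasma glycoprotein, ranked first among genes higher in the male, at -4.26 (-4.41 to -4.12) at W12 and -4.12 (-4.21 to -4.03) at W92. For enzyme genes the ratios were -2.71 and -2.71 for Cyp4b1 (ENSMUSG00000028713), -3.04 and -2.44 for Cyp2e1 (ENSMUSG00000025479), and -2.90 and -2.27 for Fmo5. The organic anion transporter gene Slc22a6 had ratios of -1.37 and -1.48, and the steroid dehydrogenase gene Akr1c21 had -1.16 and -1.62. Pigr, which carries immunoglobulin across epithelia, had -1.67 and -2.75. Havcr1, a tubular injury marker, had -2.12 and -1.13. The remaining genes were Cyp24a1 and Tm4sf20, between -2.94 and -1.05. In the W12 and W92 female sections Tm4sf20 lay at 2.62 and 3.91 times the mean control probe and Hrg at 5.82 and 5.32, so background limits their ratios too.

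**Figure D1:**
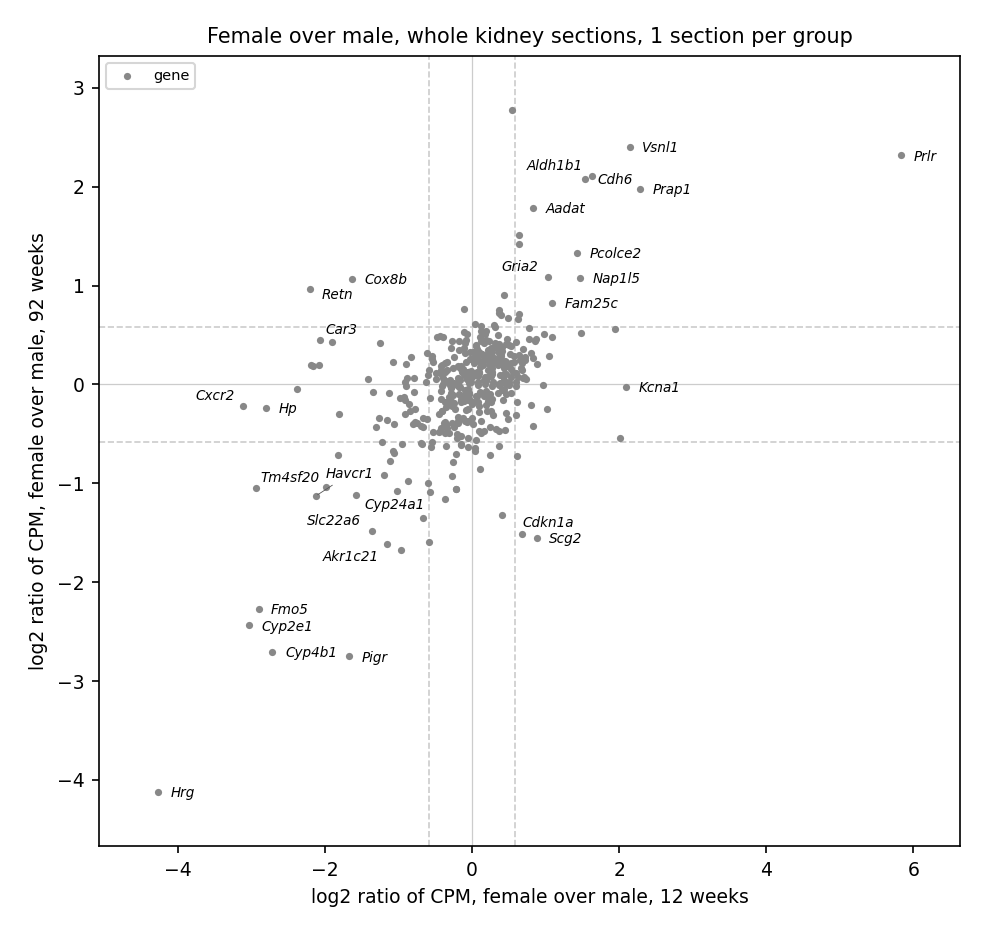
Log2 female over male CPM of each measured gene (points) at W12 on the x axis and at W92 on the y axis, with the named genes labelled. Prlr lies at 5.83 and 2.32, and Hrg at -4.26 and -4.12.

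Gene lists set before the data were examined gave the following medians of the log2 ratio at W12 and W92, in that order. The male-biased kidney list (Akr1c21, Cyp4b1, Cndp2 and Cyp2e1 measured) had -2.01 and -2.03, at percentiles 0.035 and 0.01 of 10000 random lists matched on expression. The female-biased kidney list (Aadat, Gatm and Prlr measured) had 0.83 and 1.79, at percentile 99.8 at both ages. The list of proximal tubule transport and metabolism had 0.27 and 0.11, and both were negative with mean per cell scaling. Tubular injury had -0.08 and -0.26, senescence and secretory phenotype -0.42 and -0.07, and cell cycle -0.58 and -0.32. Extracellular matrix and fibrosis had 0.11, which was negative with mean per cell scaling, and -0.18. The T and NK cell list had 0.08 and 0.01, which were negative with mean per cell scaling, the value at W92 also with median-of-ratios scaling. The macrophage and dendritic cell list had -0.49 and 0.12, the value at W92 being negative with mean per cell scaling. Neutrophil genes had -1.07 (percentile 0.445, 3 of 3 genes at least 1.5-fold higher in the male) and -0.08.

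Among lists for structures of the kidney, the podocyte list had 0.68 (percentile 99.6) and 0.20, and intercalated cell 0.36 and 0.34. Distal tubule and connecting tubule had 0.41 and -0.43 (percentile 1.405), and smooth muscle and pericyte 0.43 (percentile 98.8) and -0.24 (percentile 3.17). Collecting duct had 0.27, which was negative with mean per cell scaling, and 0.26. The endothelial list had 0.03 and 0.10, both negative with mean per cell scaling and the value at W12 also with median-of-ratios scaling. Urothelium had -0.68 (percentile 1.73) and -0.60 (percentile 1.21), and the value at W92 was positive on the higher-x side of the sections. Lists with fewer than 3 measured genes are given by gene. Of the steroid and hormone receptors, Prlr is given above. Of the thick ascending limb list Umod had 0.59 and -0.02, and Kcnj1 had 0.09, which was negative with mean per cell scaling, and 0.24. The B and plasma cell gene Ms4a1 had -0.67 and -0.34 and the adrenal gene Cyp11a1 0.24 (negative with mean per cell scaling) and 0.44. The adipocyte gene Retn had -2.20 and 0.97. The lists for MHC class II, lymphoid organisation, interferon response, and immediate early and heat shock genes had 0 genes on the panel.

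The same question was put to cells of the proximal tubule, the segment that reabsorbs most of the filtrate. Proximal tubule-like cells made up 26.1% of cells in the W12 female, 28.5% in the W12 male, 30.01% in the W92 female and 28.1% in the W92 male section. Different clusters held them in the sexes: 1 of them (cluster 6) took 6.30% and 10.5% of cells in the female sections and 0.06% in each male section. Another (cluster 12) took 6.35% and 5.63% in the male sections, against 0.527% and 0.690% in the female. Cluster 15 took 7.22% and 5.83% in the male, against 0.532% and 0.695% in the female. Of 304 genes measured in these cells in every pair, 35 were higher in the female and 22 in the male at both ages. The female excess at W12 and W92 was 6.68 and 5.80 for Cox8b, a mitochondrial gene that lay mainly in adipocyte-like cells in every section but the W12 female. It was 5.20 and 4.97 for Cdh6, and between 2.76 and 4.18 for Vsnl1, Prap1, Aldh1b1 and Pcolce2. The male excess was led by Hrg, at -4.38 and -4.42, and Fmo5, at -4.39 and -4.04, and lay between -4.56 and -2.09 for Cyp2e1, Cyp4b1, Pigr and Tm4sf20.

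Levels in proximal tubule-like cells differed with depth below the outline of the section. Between 0 and 500 µm, Prlr was at 1894 CPM in the W12 female and 34.9 CPM in the W12 male section, and at 1902 CPM and 45.9 CPM at W92. Between 1000 and 1500 µm it was at 8749 and 72.9 CPM at W12 and at 10054 and 2813 CPM at W92. The genes plotted by depth were chosen after their values were seen.

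**Figure D2:**
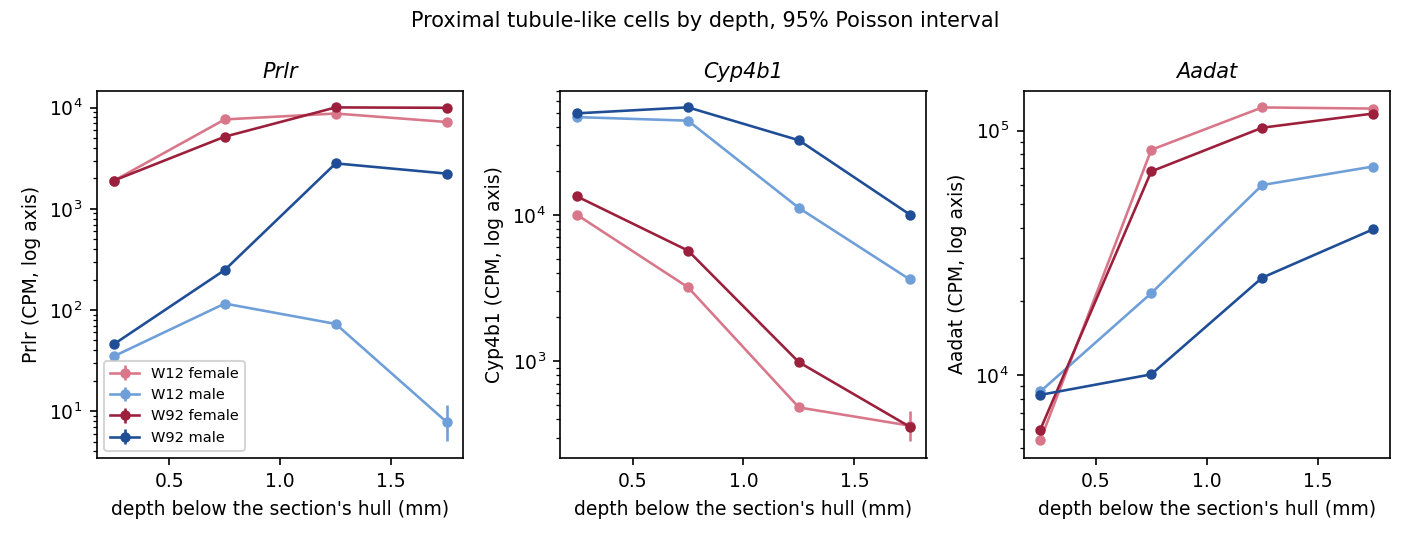
CPM (log axis) of each plotted gene in proximal tubule-like cells by depth in mm below the hull of the section, with 1 line per section and exact 95% Poisson intervals. Prlr in the W92 male section goes from 45.9 CPM in the outermost bin to 2813 CPM between 1000 and 1500 µm.

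In the other named classes, Cyp2e1 was among the leading male-higher genes of 9 classes, Cyp4b1 of 7 and Akr1c21 of 4. Aadat was among the leading female-higher genes of 4 classes, and Ccdc80 and Prlr of 3 each. Most of these are abundant proximal tubule genes, and transcripts of neighbouring cells assigned by segmentation were not removed. Within podocyte-like cells, 6 genes were higher in the female and 22 in the male at both ages, and within endothelial-like cells 2 and 9. In the remaining classes, from 0 to 6 genes were higher in the female, with 0 in adipocyte-like cells, and from 6 to 18 in the male.

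The labels also set the question of how expression differs between W12 and W92 in each sex. In the female sections, 467 genes were measured, of which 173 were at least 1.5-fold higher and 41 lower at W92. In the male sections, 468 genes were measured, with 149 higher and 26 lower. In both sexes, 123 genes were higher and 13 lower. The share of calls that were higher was 80.8% in females and 85.1% in males, against 61.8% and 62.6% with median-of-ratios scaling. The median of all genes was 0.22 and 0.20 with CPM, -0.03 and -0.04 with median-of-ratios scaling, and 0.52 and 0.28 with mean per cell scaling. Negative control probes, which match no mouse transcript, were also higher at W92, by a log2 CPM ratio of 1.09 in females and 0.93 in males. The section titles carry different dates by age, and the unassigned codeword is named differently, so age cannot be told apart from preparation or run. At W92 the dates of the female and male sections differ too, so the same holds for sex at W92 and for a change of the sex ratio with age.

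Prg2 (ENSMUSG00000027073), which encodes a granule protein, had log2 ratios of W92 over W12 of 4.08 (3.90 to 4.27) in females and 6.08 (5.90 to 6.28) in males. Tnfrsf17, the B cell maturation antigen gene, had 2.10 and 2.26, and Ms4a1, which encodes CD20, had 2.36 and 2.02. Cd5l (ENSMUSG00000015854), a secreted macrophage protein gene, had 4.81 and 3.55, from 0.945 and 0.980 times the mean control probe at W12. The complement gene C3 (ENSMUSG00000024164) had 2.27 and 2.08, and the imprinted gene Nnat 2.53 and 2.63. Away from hilar fat, Nnat had 0.43 and 0.63. Cdkn2a (ENSMUSG00000044303), a cell cycle inhibitor gene linked to senescence, had 2.07 and 2.12, and Snap25, Apoc4 and Tmem59l had between 1.85 and 2.65. A second panel entry of Cdkn2a, Cdkn2a-P16isoform, lay at 0.375 and 0.892 times the mean control probe in the W12 female and male sections. In the W92 female and male sections it lay at 2.85 and 1.42 times, also close to background. Cdkn2a, Snap25 and Apoc4 lay between 0.690 and 3.32 times the mean control probe in the sections, so their counts are close to background. So are those at W12, in the female and male sections, of Prg2 (3.85 and 2.56 times), Tnfrsf17 (3.57 and 3.24) and Tmem59l (2.40 and 4.07).

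Genes lower at W92 in both sexes had smaller ratios. Krt13 (ENSMUSG00000044041), a keratin gene of the urothelium, had -1.07 and -1.21. Sod3 (ENSMUSG00000072941), the extracellular superoxide dismutase gene, had -1.01 and -1.21, and Tubb3 and Chn2 had between -0.98 and -0.83. The transcription factor genes Myc and Bcl6 had -1.49 and -1.21 in females and -0.70 and -0.69 in males. Ttn, Cldn7, Slc14a1 and Gp2 had between -1.44 and -0.61.

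**Figure D3:**
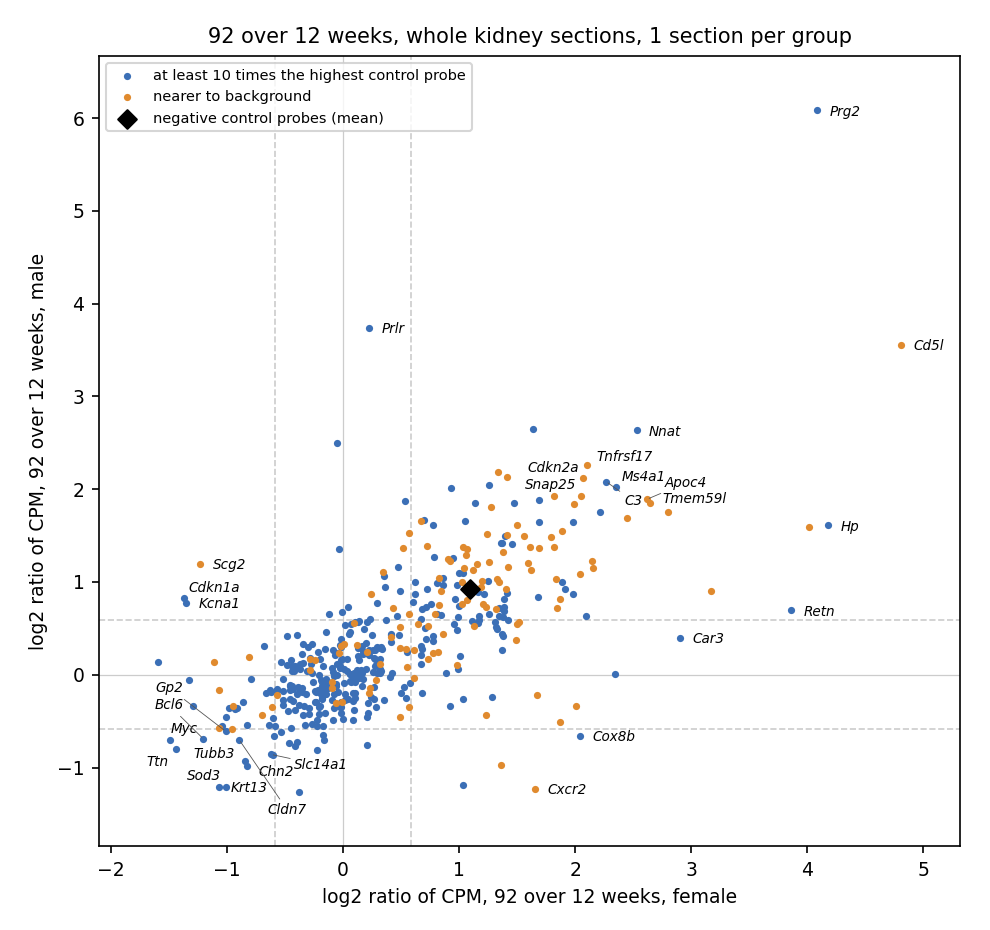
Log2 W92 over W12 CPM of each measured gene (points) in females on the x axis and in males on the y axis, with the mean of the negative control probes as a black diamond and the named genes labelled. More points lie above 0 on both axes than below, and the control probes lie at 1.09 and 0.93.

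In the gene lists, the medians of the log2 ratio of W92 over W12 in females and males follow in that order. T and NK cell genes had 1.36 (percentile 93.2) and 1.42 (percentile 97.6), with 5 of 5 genes at least 1.5-fold higher in each sex. Macrophage and dendritic cell genes had 1.26 (percentile 95.6) and 0.65 (percentile 85.9). Tubular injury genes had 0.86 (percentile 90.6) and 0.49 (percentile 85.8), and neutrophil genes 1.35 (percentile 89.14) and -0.26 (percentile 4.265). Podocyte genes had -0.54 (percentile 4.24) and -0.16, and urothelium genes 0.29 and 0.28. The direction of these 6 lists was the same under every scaling tried. Over 12 alternative settings, the male value of neutrophil genes was positive in 3 (-0.61 to 0.19). That of urothelium genes was negative in 2 (-0.60 to 1.01). Male-biased kidney genes had 0.16, which was negative with median-of-ratios scaling, and 0.39 (percentile 99.4). Female-biased kidney genes had 0.20, negative with median-of-ratios scaling and without the 5 most abundant genes, and -0.17, positive without those 5 genes. Proximal tubule transport and metabolism had 0.00, negative with those same 2 settings, and 0.10, negative with median-of-ratios scaling.

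Extracellular matrix and fibrosis had 0.21, which was negative with median-of-ratios scaling, and 0.38. Senescence and secretory phenotype had 0.50 and 0.01, the male value being negative with median-of-ratios scaling and with background subtracted. Cdkn2a, given above, is on this list but not in these medians, as it was not measured in every pair of sections. Cell cycle had 0.00, negative with 3 of the 4 other scalings, and -0.34 (percentile 1.74). Smooth muscle and pericyte had -0.40 (percentile 1.72) and 0.23, and distal tubule and connecting tubule had -0.35 and 0.22, both male values being negative with median-of-ratios scaling. Collecting duct had -0.02, positive with mean per cell scaling, and 0.00, negative with median-of-ratios scaling. Intercalated cell had -0.22 and -0.16, and endothelial -0.14 and -0.20, both female values being positive with mean per cell scaling. By gene, Umod had -0.15, positive with mean per cell scaling, and 0.46. Kcnj1 had 0.08, negative with median-of-ratios scaling, and -0.07, positive with mean per cell scaling. Cyp11a1 had 0.49 and 0.28.

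In proximal tubule-like cells, 63 genes were higher and 12 lower at W92 in both sexes. Cyp24a1, which encodes the enzyme that inactivates vitamin D hormones, had 2.10 and 1.75. Other leading genes were Tff2, Prg2 and 6330403K07Rik, with ratios of at most 3.82. Chl1, a cell adhesion gene, had -3.12 and -3.11, Sod3 had -1.27 and -1.37, and Col8a1, Anxa8, Myc and Folr2 had between -2.68 and -1.01. Across the other classes, Cyp24a1 was among the leading W92-higher genes of 4 and Prg2 of 3. In podocyte-like cells the chemokine gene Ccl2 had 3.36 and 4.41, and Havcr1 had 7.11 (5.55 to 9.39), from 3 transcripts in the W12 female section, and 4.45. In lymphoid-like cells Tnfrsf17 had 4.71 (3.78 to 5.85) and 5.30 (4.17 to 6.75), from 9 and 6 transcripts at W12, and Tnf had -1.15 and -1.23. Prg2 leads the genes that define the lymphoid-like cluster, so its ratio there is not given.

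A further comparison is whether the sex ratio was alike at both ages, which no test could address here. The sex ratio of Prlr was smaller at W92. Its W92 over W12 log2 ratio was 3.74 in males and 0.22 in females, the female value being negative with median-of-ratios scaling. Kcna1, Scg2 and the cell cycle inhibitor gene Cdkn1a had ratios from 0.68 to 2.10 at W12 and from -1.55 to -0.02 at W92. In the opposite direction, the fat-cell genes Retn, Hp and Car3, with Cox8b, had ratios from -2.80 to -1.63 at W12 and from -0.23 to 1.07 at W92. The neutrophil receptor gene Cxcr2 had -3.11 and -0.22. Cxcr2 lay at 3.10 times the mean control probe in the W12 female and Scg2 at 2.28 times in the W92 female section, close to background. Without cells within 200 µm of grouped adipocyte-like cells, Retn had 0.00 at W12 and 0.39 at W92, and Cox8b had 4.53 and 3.29. There were 746 cells within that distance in the W12 female, 5445 in the W12 male, 13688 in the W92 female and 14208 in the W92 male section.

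The composition of the sections was compared through cell classes, named by fixed marker genes. B, plasma, T or NK-like (lymphoid-like) cells made up 0.732% of cells in the W12 female, 0.874% in the W12 male, 2.02% in the W92 female and 2.89% in the W92 male section. The W92 over W12 ratio of these shares was 2.76 (2.60 to 2.93) in females and 3.31 (3.13 to 3.50) in males. Macrophage or dendritic-like cells made up 1.91%, 2.75%, 3.49% and 3.18% in the same order, with ratios of 1.83 (1.76 to 1.90) and 1.16 (1.11 to 1.20). No cluster was named neutrophil, and this class held 33.3%, 52.6%, 35.8% and 39.8% of the transcripts of Csf3r, a gene of the neutrophil list. Its shares and ratios may therefore include neutrophils. Cells with at least 3 Cd3e plus Cd3d transcripts, from genes of the T cell receptor complex, made up 0.307%, 0.392%, 0.944% and 1.04% of cells. In thick ascending limb-like cells, which should lack these genes, the shares were 0.0154%, 0.0356%, 0.0333% and 0.0143%. Cd3e and Cd3d were among the genes used to assign cells, so these low shares are partly set by the assignment. They are no independent measure of background.

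Endothelial-like cells made up 7.98%, 7.27%, 5.32% and 5.11% of cells in the same order, with W92 over W12 ratios of 0.667 and 0.703. An unnamed cluster (cluster 7), led by endothelial genes such as Gpihbp1 and Kdr beside proximal tubule genes, made up 3.55%, 4.56%, 3.81% and 5.75%, with ratios of 1.07 and 1.26. The size of the endothelial-like difference therefore depends on which clusters are named. Adipocyte-like cells made up 0.136%, 0.601%, 1.38% and 0.936%. Thick ascending limb-like cells made up 19.4%, 16.7%, 17.1% and 15.8%, and podocyte-like cells 1.41%, 1.12%, 1.24% and 0.997%. Cells of clusters that could not be named made up 19.7%, 21.4%, 18.8% and 21.8%. Shares of a whole sum to 100%, so a higher share of 1 class lowers the others, and doublets were not called.

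**Figure D4:**
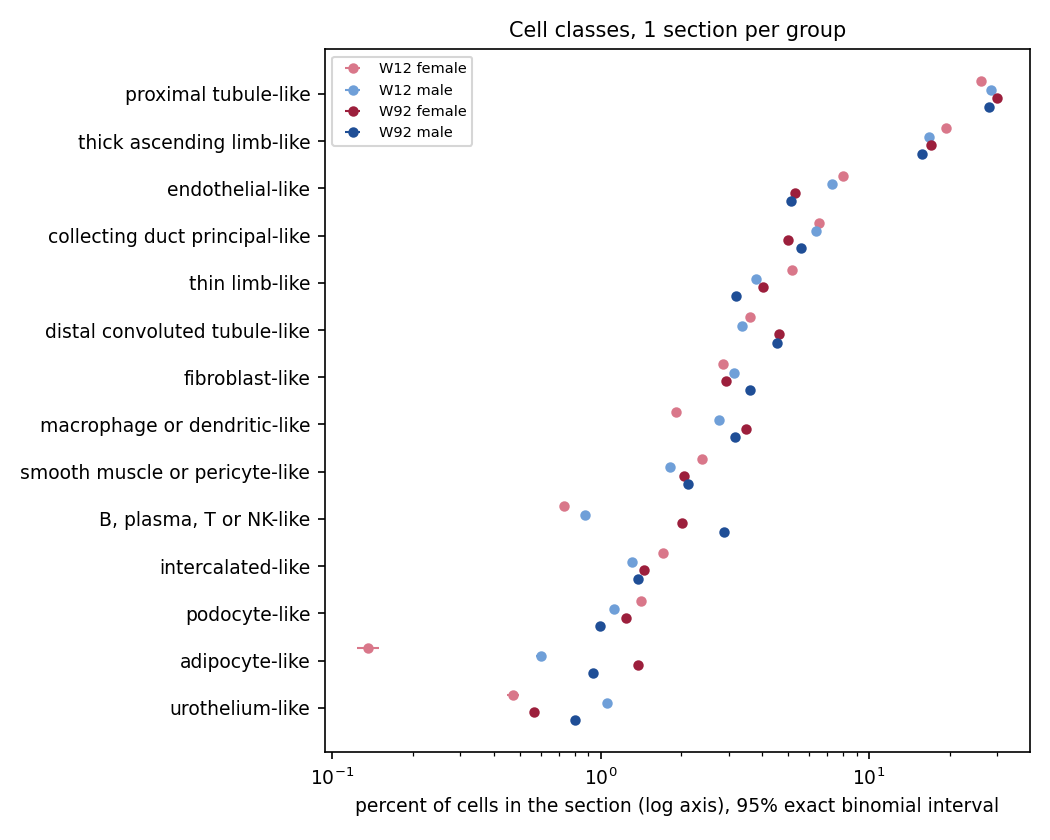
Percent of cells in each class (log axis) per section, with exact 95% binomial intervals. Lymphoid-like cells lie at 0.732% and 0.874% in the W12 sections and at 2.02% and 2.89% in the W92 sections.

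Lymphoid-like cells were also compared by position. Aggregates were density-linked groups of at least 50 such cells. They held 36.3% (34.4 to 38.3) of lymphoid-like cells in the W12 female, 10.9% (9.74 to 12.1) in the W12 male, 43.9% (42.9 to 45.0) in the W92 female and 54.7% (53.8 to 55.6) in the W92 male section. There were 5, 3, 13 and 28 aggregates in the same order, and the largest held 508, 182, 859 and 1223 cells. The intervals treat cells as independent, which grouped cells are not. Away from hilar fat, a setting chosen after the data were seen, aggregates held 36.5%, 11.0%, 37.4% and 51.4% in the same order. The female sections were then close to each other, and the difference between ages was left in males alone. With a minimum of 200 cells the W12 male section had 0 aggregates, since its largest at the main setting held 182 cells.

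**Figure D5:**
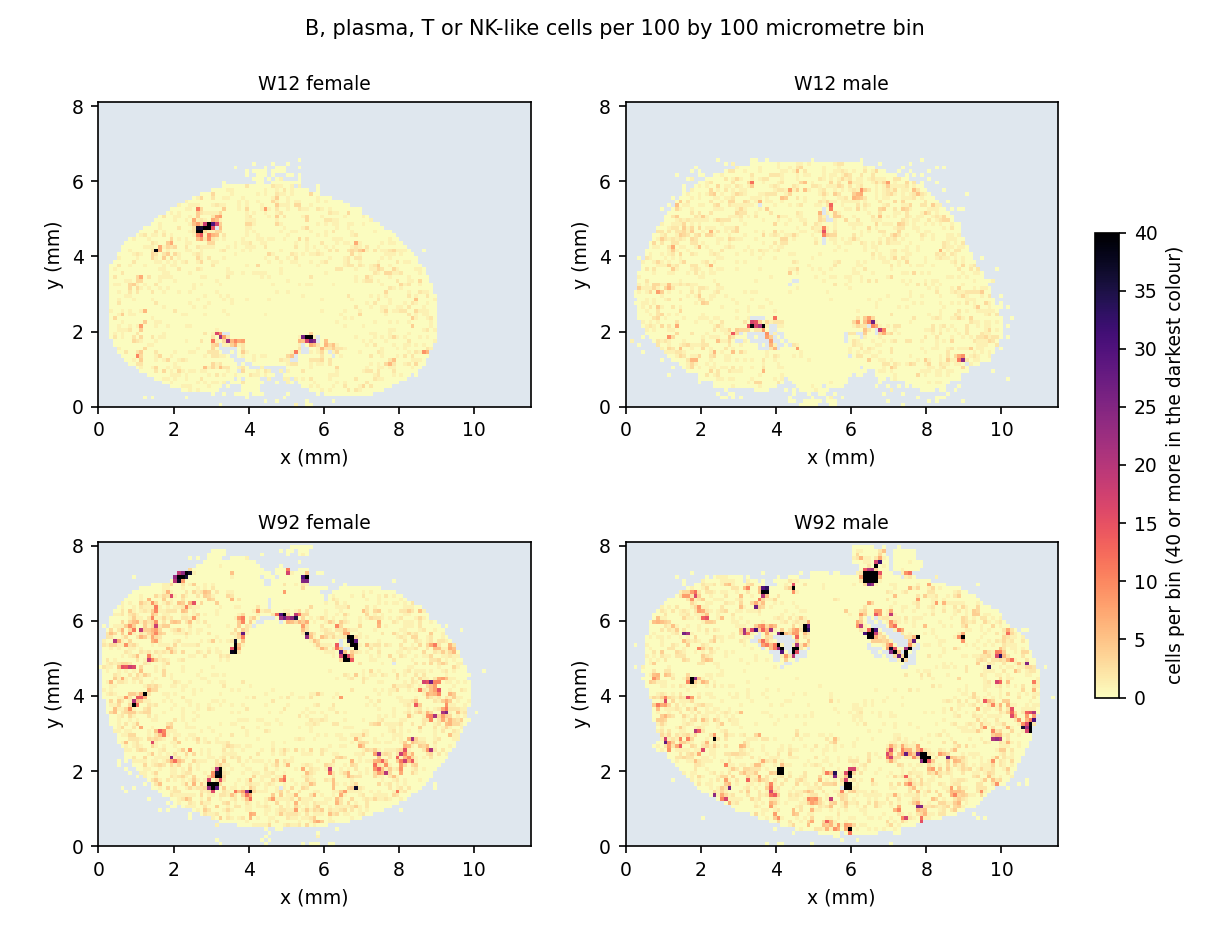
Lymphoid-like cells per bin of 100 by 100 µm in each section, with x and y positions in mm. The W92 male section has 28 aggregates and the W12 male section 3.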

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

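The tests on genes far above and near background, on the most abundant genes, on which side sex-biased genes lie, and both tests on Prlr in females were chosen after the result was seen, and so were the settings without cells near hilar fat.

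Sex ratios of 5 genes had opposite directions at the 2 ages, each past 1.5-fold, and the difference was not tested, as each group has 1 section. The log2 female over male ratio at W12 and W92 was 0.68 and -1.52 for Cdkn1a, -1.63 and 1.07 for Cox8b, 0.61 and -0.72 for Lyve1, -2.20 and 0.97 for Retn, and 0.88 and -1.55 for Scg2. The log2 W92 over W12 ratio had opposite directions in females and males for 7 genes, again untested. It was -1.37 and 0.82 for Cdkn1a, 2.04 and -0.66 for Cox8b, 1.66 and -1.23 for Cxcr2, 1.36 and -0.97 for Hc, -1.35 and 0.77 for Kcna1, -1.23 and 1.20 for Scg2, and 1.03 and -1.19 for Socs2. Without cells near hilar fat, the sex ratio of Cox8b at W12 was 4.53 and that of Retn 0.00, and the age ratio in males was 0.97 for Cox8b, 0.13 for Kcna1 and 0.18 for Scg2, so these no longer had opposite directions past 1.5-fold. Lyve1, Hc and Socs2 are outside the rule for named genes and are given because their directions differ. Hc lay between 1.22 and 4.55 times the mean control probe in the sections, so background limits its ratios.

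Control features are left out of the main ratios and serve only as a measure of background, and they gave signal in every section. Negative control probes gave 3.97 transcripts per 1000 cells in the W12 female, 5.67 in the W12 male, 10.3 in the W92 female and 11.4 in the W92 male section. Negative control codewords gave 5.94, 9.32, 18.7 and 21.8 in the same order, and the unassigned codeword 0.157, 0.212, 0.852 and 0.495.

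The first pattern weighed is that 123 genes were higher and 13 lower at W92 in both sexes. Higher background in the W92 sections is argued against for genes far above background, where 63 were higher and 12 lower, a ratio of 5.25 (2.80 to 10.7), as is more hilar fat, since 90 genes were higher without cells near it, and a few abundant genes, since the ratio was 9.31 (5.24 to 18.0) without the 5 most abundant. For the 60 higher genes near background it cannot be told apart: 86.7% (75.4 to 94.1) stayed higher after subtraction of the mean control probe, but 45% after that of the highest. A first test of the scaling did not decide either, as median-of-ratios scaling gave 82 higher and 35 lower, a ratio of 2.34 (1.56 to 3.59), so the size of the excess depends on the scaling. Age cannot be told apart from preparation or run, and a biological difference with age stays open, untested.

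The second pattern is the higher share of lymphoid-like cells at W92. A section plane through hilar tissue is argued against as its whole cause, since the smaller ratio of W92 over W12 was 2.51 without cells near hilar fat. Cells with at least 3 Cd3e plus Cd3d transcripts had ratios of 3.08 in females and 2.65 in males. These ratios cannot decide on background counted in cells, since negative control codewords per cell rose 3.14 and 2.34 times themselves. Negative control probes per cell rose 2.61 and 2.01 times. Cd3e lay between 79.3 and 113 times the mean control probe in the sections, and Cd3d between 22.2 and 31.1 times. Background at that mean would be a small part of their transcripts, though these levels were looked at after the result was seen. Run and age cannot be told apart, and with 1 mouse per group a difference between mice in place of ages may explain it. Age biology stays open, untested.

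The third pattern is Prlr, higher in the W92 male than in the W12 male section. A swap of the sexes at a single age is argued against by 53 other genes at least 2-fold apart between the sexes at W12. Of these, 75.5% (61.7 to 86.2) lay on the same side at W92, where the limit of 60% was also set after the result was seen. Male sections with exchanged ages would also leave the sides of sex-biased genes alike, so such a mislabelling was not tested. In the W92 male section Prlr was 14.4 times as high in proximal tubule-like cells, at 1219 CPM, as in other cells, at 84.9 CPM. Prlr is among the genes used to assign cells, so this ratio is partly set by the assignment. It cannot decide alone on background spread over the section. Within proximal tubule-like cells of that section, Prlr was at 45.9 CPM between 0 and 500 µm and at 2813 CPM between 1000 and 1500 µm. These values, looked at after the result was seen, argue against an even spread. A probe or run difference that multiplies every section alike is argued against, since the female log2 difference between ages was 0.0599 of the male one. One that adds the same level to every section cannot be told apart by section sums, since the female rise was 0.774 of the male one in CPM but -0.112 of it with median-of-ratios scaling. Values by depth, looked at after the result was seen, argue against a level added evenly to all cells. In proximal tubule-like cells between 0 and 500 µm, Prlr went from 34.9 to 45.9 CPM in males and from 1894 to 1902 CPM in females. A level added to some cells alone stays open. The title of the W92 male section carries its own date, so a preparation or run difference of that section alone stays open. A difference between mice and an effect of age in males stay open too, untested.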

How the results depend on the processing

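The settings without cells near hilar fat, without Prg2 in the assignment, and with genes at least 10 times the highest control probe (in every section, or on the mean) were chosen after the data were seen, and the rest were planned. No paired analysis was possible because each group has a single section from a single mouse. The cause was not tested for any of the values below, except that a higher threshold or a filter on genes leaves fewer genes to call.

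With no filter on cells, a minimum of 30 transcripts per cell, no filter on genes, background subtracted, and without the 5 most abundant genes, each of the 10 counts of genes stayed within 1.5 times its value. The class ratios of lymphoid-like and macrophage or dendritic-like cells moved within their counting intervals with a minimum of 30 transcripts, without centring and without Prg2 in the assignment. Equal weight per class was planned for the counts by age alone, and thinned sums give a value for proximal tubule-like cells alone. Over the settings run, genes higher at W92 in both sexes numbered 51 to 147 and genes lower 2 to 35. The ratio of the lymphoid-like share was 2.32 to 3.44 in females and 2.24 to 4.33 in males, and that of the macrophage or dendritic-like share 1.81 to 2.57 and 1.02 to 1.56.

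With a 2-fold threshold, 16 genes were higher in the female and 38 in the male at W12, 15 and 24 at W92, and 8 and 12 at both ages. At W92, 60 genes were higher and 2 lower in both sexes, and 11 were higher in the male in proximal tubule-like cells. With mean per cell, 18 genes were higher in the female and 137 in the male at W12, 9 in the female at both ages, 6 were lower at W92 in both sexes, and 43 were higher in the male in proximal tubule-like cells. With median-of-ratios scaling 35 genes, and with equal weight per class 4, were lower at W92 in both sexes. Equal weight per class also left 26 genes higher in the female and 62 in the male at W12, and 14 and 34 at W92. With genes at least 10 times the highest control probe in every section, which drops genes low in any section, 31 were higher in the female and 44 in the male at W12, 20 in the female at W92, 9 in the female at both ages, and 51 at W92 in both sexes. With that minimum on the mean, 63 were higher at W92 in both sexes. Away from hilar fat, 56 genes were higher in the female and 55 in the male at W12, and 34 and 33 at W92. On the lower-x side, 54 genes were higher in the female at W92 and 73 at W92 in both sexes.

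For lymphoid-like cells, the W92 over W12 ratio in females and males was 2.58 and 2.24 with 2 marker transcripts, 2.32 and 2.37 on the lower-x side of the sections, 3.44 and 4.33 on the higher-x side, and 2.51 and 3.06 away from hilar fat. In males it was 2.86 at double resolution and 2.95 when thinned to 30 transcripts. For macrophage or dendritic-like cells it was 2.57 and 1.56 with 2 marker transcripts and 1.91 and 1.02 at double resolution, and in males 1.04 on the lower-x and 1.28 on the higher-x side. Aggregates in the W12 female, W12 male, W92 female and W92 male sections held 29.7%, 0%, 36.9% and 38.9% with at least 200 cells, and 27.0%, 7.40%, 39.1% and 49.2% with a distance of 30 micrometres. Away from hilar fat they held 36.5%, 11.0%, 37.4% and 51.4% in that order.

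Reversed values away from hilar fat were those of Cox8b at 4.53 for sex at W12, -0.27 for age in females and 0.97 in males, Krt5 at 0.32 for sex at W92 and -0.092 for age in males, and Nnat at 0.55 and 0.35 for sex at W12 and W92. On the lower-x side, Retn was reversed at -0.36 for age in males. On the higher-x side, reversed values for sex were those of Cox8b at 0.23 (W12) and -0.53 (W92), and at W92 of Krt19 at 0.11, Krt5 at 0.72, Retn at -0.90 and the urothelium list at 0.11. For age in males they were those of Cox8b at 1.96 and Krt5 at -0.90. No other value of a named gene or list that was called changed sign. Of values of single genes and lists, 400 moved by more than counting error away from hilar fat, 643 with mean per cell, 570 with median-of-ratios scaling, 520 on the lower-x and 513 on the higher-x side. Another 228 moved without the 5 most abundant genes, 65 with background subtracted, 26 with the proximal tubule class without centring, and 12 and 9 with the minimum over control probes in every section and on the mean.

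Depth limits genes with few transcripts: under 300 in the richer section of a pair, genes were left out. At the depths of these sections, simulated 2-fold differences were recovered in 100% of genes. The simulation holds counting error alone, and variation between mice was not measured.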

Other observations

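The setting that left Prg2 out of the assignment and the thinning of cells were chosen after the result was seen, and the test on Tnfrsf17 was set before its result.

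Prg2 had 257 transcripts in the W12 female, 232 in the W12 male, 6686 in the W92 female and 20633 in the W92 male section. Of these, 9.73% and 1.72% lay in lymphoid-like cells at W12, and 71.9% and 77.0% at W92, though Prg2 also leads the genes that define that cluster. A hypothesis is that plasma cells may carry the Prg2 signal at W92. Among lymphoid-like cells of the W92 female section, 45.5% of the 635 with at least 3 Prg2 transcripts had a Tnfrsf17 transcript, against 1.71% of those with none, a ratio of 26.6. In the W92 male section it was 23.6% of 2039 against 1.26%, a ratio of 18.7, and 5 or more in both sexes was the limit set. With cells thinned to 50 transcripts the ratios were 30.9 and 14.8. Sdc1, another plasma cell gene, was seen in 94.3% and 95.3% of the cells with Prg2, against 21.2% and 27.1%, and Cd3e in 26.9% and 20.2%, against 61.2% and 55.9%. Against plasma cells alone, the B cell gene Ms4a1, which plasma cells lose, was also seen more often in the cells with Prg2, in 35.6% and 40.7% against 18.3% and 22.1%. These shares cover lymphoid-like cells alone, and the Prg2 transcripts outside them were not tested. Whether plasma cells, other B cells or cells of another kind carry the signal stays open. Whether such cells transcribe Prg2 or the probes bind another of their transcripts cannot be told from these counts.

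An unnamed cluster whose leading genes include Gabrp and Slc34a2 (cluster 29), chosen after its values were seen, took 0.215% of cells in the W12 female, 0.160% in the W12 male, 0.618% in the W92 female and 1.35% in the W92 male section. Another unnamed cluster (cluster 23) held 73.5% of the Cd5l transcripts of the W92 female and 49.1% of those of the W92 male section. Of Car3 transcripts, the adipocyte-like cluster held 41.8% in the W12 female, 52.6% in the W12 male, 88.6% in the W92 female and 74.5% in the W92 male section.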
